A study of Mus musculus with 26 samples.

How the data were processed

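Gene expression was measured in mouse cells on 26 one-colour Agilent 8x60K arrays, 1 per sample. Per the labels, they cover 4 somatic cell types (pre-B cells, neural stem cells, embryonic fibroblasts of embryo day 13.5 and macrophages), the iPS cells made from each at passages 3 and 20, and the ES line E14, with 2 replicates in each of 13 groups. Reprogramming was driven by doxycycline for 15 days with colonies picked at day 20 and grown for 9 days to passage 3, and iPS cells were kept on mitomycin-treated fibroblast feeders. For ES cells the labels describe culture on feeders with serum and culture without feeders in 2i, and do not say which was used for these arrays. From each sample 500 ng of RNA with an integrity number of at least 9 was labelled.

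Per the file headers, the scanner files hold spot intensity values from Agilent Feature Extraction 10.7.3.1 with the mm9 grid annotation, with background subtracted and spatial trends removed within each array, on a linear scale and with no scaling between arrays. The table deposited by the authors holds log2 values that were scaled between arrays (medians of 6.82 to 6.89), with a background step and a way of scaling that are not stated. It has 55821 entries, of which 55681 match a non-control probe, and its values correlated with the log2 mean signal of the same array at 0.993 to 0.999, with slopes of 0.98 to 1.25. It was used as an alternative only.

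From the scanner files, 59305 non-control spots per array were read and spots that Feature Extraction marked as uneven or as deviating from their replicates were set to missing, which left 1220 of 55681 probes missing on at least 1 array. Spots of the same probe were averaged (55249 probes have 1 spot). Signals were put on the log2 scale and the 75th percentile of each array was subtracted. Probes were kept when well above background on both arrays of at least 1 group (41577 probes). Gene names came from the RefSeq symbols through the accession (27428 probes), the symbol (3483) or a synonym (507), and otherwise from the file (24263), and 89.8% of spots had the same name in the older and newer annotation. For the 8593 genes with several probes, the probe with the highest mean was used, and among called genes with several probes another probe was called the other way for 503 of 3634 in the pre-B somatic comparison, 472 of 4276 in pre-B reprogramming, 18 of 860 and 5 of 406 in the pre-B and MEF passage comparisons, and 58 of 1949 and 30 of 1546 against ES at p3 and p20. This gave 27775 genes, 18512 of them with a symbol among the reference genes.

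Negative controls read 51.54 to 102.1 and the 75th percentile of signal 432.45 to 1373.6, and 1 probe was saturated, on ES E14 replicate 1. The share of probes well above background, 48.4 to 81.6%, sets which dim genes can be measured; the number of arrays limits the precision of every difference.

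One limma model with a mean for each of the 13 groups was fitted to all 26 arrays (13 residual degrees of freedom), with empirical Bayes variances, and Benjamini-Hochberg adjustment within each comparison. Genes were called at adjusted p < 0.05 and an absolute log2 difference of at least 1 (a range of at least 1 for F tests). The comparisons were each somatic type against the mean of the 3 others, p3 iPS cells against their founder, p20 against p3 for each origin and averaged, all iPS groups of a passage against ES, F tests of origin at each passage and of origin by passage, and the genes at least 2 log2 units higher in a founder followed in iPS cells of that origin against the others. Residual spread was taken to be alike in all groups, so a group whose replicates vary more than the rest has its error understated. The difference of between-origin spread was tested exactly over swaps of passage labels. In all, 28 gene lists fixed before the data were examined were tested in 15 comparisons with camera, with a preset correlation of 0.01 and again with the correlation estimated, adjusted over the list tests of each kind of comparison. Software was R 4.3.3 with the packages limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8).

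Named genes were chosen by a rule fixed in advance. For each comparison and direction, among called genes with a usable symbol and with no overlap between the arrays of the sides, these are the 5 with the largest difference among those well above background on at least 1 array of both sides, and the 5 with the largest lower bound among those dim on every array of one side. F tests name the 10 genes with the largest range, and lists up to 4 called members with the largest difference. Pou5f1, Nanog, Sox2, Klf4, Myc, Esrrb, Zfp42, Cd19, Csf1r, Nes and Col1a1 were always eligible. The text names a selection of these.

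Alternatives set before the data were seen were normexp background correction (offset 50), quantile normalization, no filter or a strict filter on dim probes, the mean of all probes of a gene, a variance trend with robust estimation, only the arrays of the groups compared, slide as a block, the replicate number as a block, the authors' values, adjusted p with no minimum fold, founder signatures at 3 log2 units, and leaving out each array in turn. The strict filter kept only probes well above background on all 26 arrays, and so drops genes that are silent in any group. Cyclic loess, array weights, leaving out preB replicate 1 and tests within a slide were added after seeing the data.

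The code was tested on simulated data with known changes in 200 genes. Of genes changed by 3, 2 and 1 log2 units it called 61 of 66, 47 of 67 and 15 of 67 for neural stem cells, 52 of 66, 39 of 67 and 18 of 67 for the pre-B passage comparison, 63 of 66, 56 of 67 and 29 of 67 for the averaged passage comparison and 61 of 66, 43 of 67 and 12 of 67 against ES at p3, with 5, 8, 0 and 0 unchanged genes called. The F tests recovered 162 of 200 (origin at p3) and 143 of 200 (origin by passage), and 5 of 200 random lists had camera p under 0.05. The simulated genes varied independently, so that count does not test the preset correlation for lists whose members are correlated.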

Results

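Which genes set 4 mouse somatic cell types apart, what changed when each was turned into iPS cells, and what was left of those differences after 20 passages? The series holds 26 arrays: pre-B cells, neural stem cells (NSC), embryonic fibroblasts (MEF) and macrophages, the iPS cells made from each at passage 3 (p3) and passage 20 (p20), and the ES line E14, with 2 arrays per group. In the tests below, values are log2 differences ± standard error with adjusted p from limma. Levels are log2 signal relative to the 75th percentile of the array (mean ± SD). A called gene passed adjusted p < 0.05 with a log2 difference of at least 1. Where a gene was not well above background on any array of one side, the fold is given as "at least", a lower bound that sets each array of the dim side no lower than its dimmest signal well above background. A gene counted as well above background where any of its probes was. The probe whose level is given can thus be dim without an "at least", and such a fold is uncertain. Counts of list members are higher, lower and not called. Where adjustment over the list alone gave other counts, they follow. Every list also has a camera adjusted p, which was lost for most lists once the correlation within the list was estimated (15 of 420 list tests passed then, 173 with the preset correlation). Labels do not say whether the replicates of a group were separate cultures, so the p values measure only the spread between these samples, which may be technical.

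On all arrays but 1, signal was of a similar kind. On preB replicate 1, 81.6% of probes were well above background and the median signal was 317.8, against 66.6% on preB replicate 2, and 48.4 to 62.9% with medians of 28.59 to 84.48 on the other groups. The pair of preB arrays correlated at 0.947, other replicate pairs at 0.98 to 0.993. Their root mean square log2 differences were 1.62 and 0.49 to 0.78, so the pooled error is understated for pre-B cells. In NSC iPS p3, preB iPS p20 and macrophages iPS p20, neither array correlated best with its replicate. In NSC iPS p20 and MEF iPS p20 only 1 array did. The best matches of these arrays were iPS arrays of another group. The slides and the groups were tied: preB arrays were on slides 1 and 2, the 3 other somatic types and ES E14 on slide 3, and all iPS arrays on slides 4 and 5, each of which held both passages. For every origin, slide 4 held p3 replicate 1 with p20 replicate 2, and slide 5 held p3 replicate 2 with p20 replicate 1. Each passage change within a slide thus compares arrays of different replicate number.

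To describe the starting cells, each somatic type was compared with the mean of the 3 others (2 arrays against 6). In pre-B cells, genes of the early B lineage led. Cd79b, part of the B cell receptor, was higher by 12.36±0.19 (adjusted p = 1.5e-15, 5240-fold, level 7.57±0.29 against -4.79±2.85), and the pre-B gene Vpreb3 by 12.35±0.24 (5210-fold). Mzb1, a chaperone of antibody assembly, was higher by 3500-fold, the B cell surface gene Cd19 by 11.76±0.41 (3470-fold) and the coactivator Pou2af1 by 11.64±0.6 (3190-fold). Igll1, a surrogate light chain gene, was higher by at least 3960-fold (7.01±0.25 against -7.06±0.47), the peptidase Enpep by at least 278-fold and the chemokine receptor Cxcr5 by at least 227-fold. Lower in pre-B cells were the tetraspanin Tspan7 (-7.85±0.19, 231-fold), the glycosyltransferase B3galnt1 (103-fold), the secreted protease Htra1 (102-fold), the creatine kinase Ckb (88.4-fold) and, by at least 161-fold, the radial glia gene Fabp7. Of 22 pre-B markers, 21 were higher and 1 was not called (median 8.8, camera adjusted p = 6.71e-12, a call that held with an estimated correlation, 0.005).

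Genes of other marrow cells were higher in the pre-B arrays too: 14 of 17, with 1 lower (adjusted p = 0.000638, and 0.0198 with an estimated correlation), among them the granulocyte genes S100a9 (10.08±0.51, 1080-fold), Ltf (221-fold) and Mpo (198-fold). Interferon response and antigen presentation genes were higher for 17 of 19 and lower for 0 (adjusted p = 2.58e-05, but adjusted p = 0.305 with an estimated correlation), led by Ifi44 (36.6-fold). Fibroblast genes, markers of another cell type, were higher for 18 of 29 and lower for 3 (adjusted p = 0.0119, adjusted p = 0.623 with an estimated correlation), including the collagens Col1a2 (59.8-fold) and Col6a1 (33-fold). NSC markers split 4, 17 and 4 (adjusted p = 6.1e-05, adjusted p = 0.282 with an estimated correlation), with the intermediate filament gene Nes lower by 49.8-fold. Imprinted genes outside the Dlk1-Dio3 cluster split 0, 14 and 12 (adjusted p = 3.05e-06, adjusted p = 0.0973 with an estimated correlation), with the zinc finger gene Plagl1 lower by 70.2-fold. Proliferation genes were 13 higher, 2 lower and 8 not called (adjusted p = 0.000211, adjusted p = 0.393 with an estimated correlation). In all, 8684 genes were higher and 4323 lower. That split turned on the scaling, at 6214 and 7617 after quantile normalization, 4643 and 5656 with the authors' values and 6437 and 5846 after cyclic loess. Weighting the arrays by quality left 8204 genes.

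Neural stem cells were marked by genes of the glial and neuronal lineages. Bex2, a brain-expressed gene, was higher by 11.46±0.28 (adjusted p = 5.5e-14, 2810-fold, level 7.26±0.02 against -4.2±3), the brain matrix gene Bcan by 11.28±0.3 (2480-fold) and the synaptic adhesion gene Lrrc4b by 2180-fold. Olig1 and Olig2, oligodendrocyte regulators, were higher by at least 2560-fold and at least 773-fold. Lower were Plac8 (-11.27±0.22, 2460-fold), the chemokine Ccl7 (2090-fold), the cytokine receptor Csf2rb (1890-fold) and, by at least 2920-fold, the antiviral gene Oas1a. NSC markers were 23 higher, 0 lower and 2 not called (median 7.14, adjusted p = 1.45e-16, 0.021 with an estimated correlation), with Sox3 (1030-fold), Sox2 (9.62±0.25, 785-fold), Nes (141-fold) and Pax6 (51.1-fold). Markers of the other founders were lower. For pre-B it was 21 of 22 (adjusted p = 2e-10, 0.005 with an estimated correlation), for macrophages 23 of 25 (24 adjusted over the list alone, adjusted p = 4.88e-14, 0.0335 with an estimated correlation). Among fibroblast genes 25 of 29 were lower and 1 higher (adjusted p = 2.22e-10, adjusted p = 0.207 with an estimated correlation). All 19 interferon response and antigen presentation genes were lower (adjusted p = 4.88e-14, adjusted p = 0.0599 with an estimated correlation), such as Oasl2 (379-fold). So were 34 of 37 Hox cluster genes (36 adjusted over the list alone, adjusted p = 2.63e-09, adjusted p = 0.287 with an estimated correlation). The other imprinted genes split 11, 6 and 9 (adjusted p = 0.0168, adjusted p = 0.393 with an estimated correlation), with Mest (424-fold) and Nnat (229-fold) higher. Called genes were 4123 higher and 5711 lower, against 3954 and 3435 with the authors' values.

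In fibroblasts, the interleukin receptor Il1rl1 was higher by 11.3±0.39 (adjusted p = 6.1e-12, 2520-fold, level 7.32±0.13 against -3.98±2.75). The matrix proteins Mgp (11.23±0.31, 2400-fold) and Postn (11.02±0.7, 2070-fold) followed, as did the imprinted RNA H19 (10.59±0.3, 1540-fold). The proteoglycan Dcn and the BMP antagonist Grem1 were higher by at least 1620-fold and at least 1250-fold. Lower were the nuclear pore gene Nup210 (-7.48±0.19, 178-fold), the Notch modifier Mfng (175-fold), the kinase Prkcb (-7.16±0.17, 143-fold) and the receptor Kit (at least 23.8-fold). All 29 fibroblast markers were higher (median 6.33, adjusted p = 3.59e-31, 0.0198 with an estimated correlation), with the regulator Twist2 at 953-fold. Hox cluster genes were 34 higher, 0 lower and 3 not called (adjusted p = 1.51e-20, adjusted p = 0.0812 with an estimated correlation), as with Hoxc6 (738-fold) and Hoxd13 (at least 171-fold). Imprinted genes outside the Dlk1-Dio3 cluster were higher for 17 of 26 and lower for 1 (17 and 2 adjusted over the list alone, adjusted p = 2.02e-09, 0.0335 with an estimated correlation). In that cluster 3 of 5 were higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0113, adjusted p = 0.143 with an estimated correlation), with Dlk1 at 235-fold and Meg3 at 207-fold. Higher too were 14 of 19 interferon genes with 0 lower (adjusted p = 1.03e-08, adjusted p = 0.154 with an estimated correlation). The p53 and INK4 pathway split 5, 0 and 8 (adjusted p = 0.000351, adjusted p = 0.172 with an estimated correlation), with the cell cycle inhibitor Cdkn2b higher by 16.7-fold. Proliferation genes were 0 higher, 9 lower and 14 not called (adjusted p = 2.28e-05, adjusted p = 0.349 with an estimated correlation). Called genes were 3260 higher and 4797 lower, against 4079 and 3542 after quantile normalization, 3009 and 2434 with the authors' values and 3923 and 3559 after cyclic loess. With normexp background correction 5216 genes were called.

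Macrophages carried phagocyte genes. The integrin Itgax was higher by 10.98±0.78 (adjusted p = 7e-09, 2030-fold, level 7.01±0 against -3.98±2.42), the fungal receptor Clec7a by 10.39±0.37 (1340-fold), the secreted Wfdc17 by 1220-fold, the proton pump subunit Atp6v0d2 by 1170-fold and the fusion gene Dcstamp by at least 46.9-fold. Lower were the matrix genes Sparc (-11.26±0.22, 2450-fold), Aebp1 (693-fold) and Fbln2 (at least 870-fold), and H19 (-8.23±0.3, 300-fold). All 25 macrophage markers were higher (median 6.6, adjusted p = 4.14e-17, 0.0198 with an estimated correlation), with the lysozyme Lyz2 at 1010-fold, the mannose receptor Mrc1 at 526-fold and the growth factor receptor Csf1r at 57.1-fold. Marrow genes were 12 higher, 1 lower and 4 not called (adjusted p = 0.000608, 0.0198 with an estimated correlation). Fibroblast genes split 2, 26 and 1 (adjusted p = 2.59e-10, adjusted p = 0.207 with an estimated correlation). NSC markers split 0, 23 and 2 (adjusted p = 5.74e-08, adjusted p = 0.138 with an estimated correlation), and Hox genes 2, 26 and 9 (29 lower adjusted over the list alone, adjusted p = 0.000291, adjusted p = 0.496 with an estimated correlation). Immediate early genes were higher for 9 of 14 and lower for 2 (adjusted p = 0.000638, adjusted p = 0.25 with an estimated correlation), among them Egr2 (27.6-fold) and Atf3 (21.8-fold). In total 4639 genes were higher and 5311 lower. Within slide 3 alone, with the pre-B arrays left out, the tests called 9861 genes for NSC, 7092 for MEF and 10281 for macrophages. With slide as a random block they called 9988, 8216 and 10029, and 12598 for pre-B. Requiring a probe well above background on all 26 arrays left 5058, 3951, 2973 and 4835 genes for pre-B, NSC, MEF and macrophages. That strict filter tested 14984 genes in place of 27775. Genes dim in any group drop out of it, markers silent in another cell type among them, so lower counts follow in part by design.

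**Figure D1:**
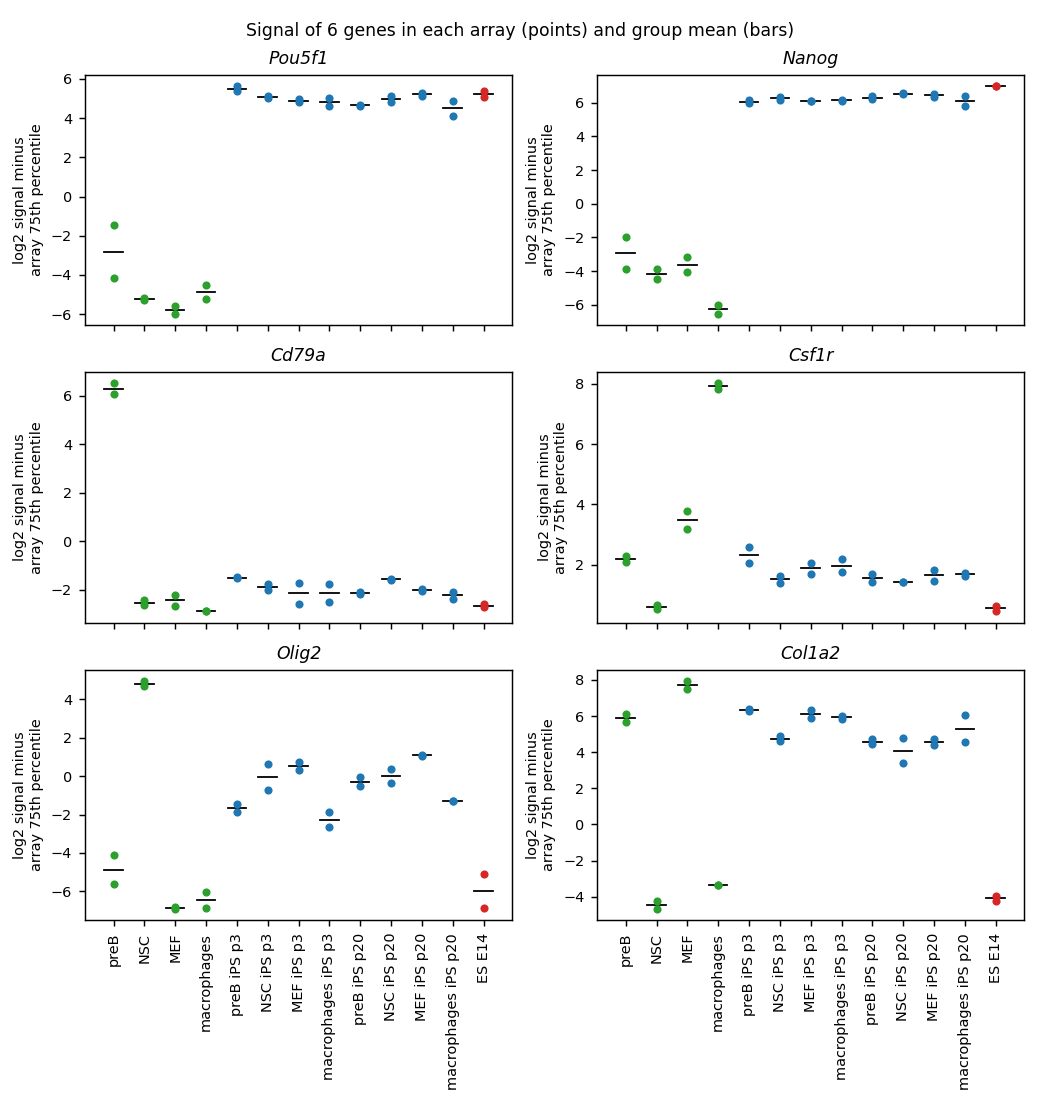
Levels of 6 genes on each array (log2 signal relative to the 75th percentile of the array, y axis) by group (x axis): Pou5f1 lay at 4.52 to 5.51 in the iPS group means and 5.24±0.21 in ES, while Cd79a, Csf1r and Olig2 were highest in pre-B cells, macrophages and NSC, and Col1a2 was high in MEF, pre-B and iPS arrays.

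How far did each founder move on becoming iPS cells? Each p3 group was compared with its founder cell type (2 arrays against 2, on different slides and scan days). ES arrays shared slide 3 and its scan day with the NSC, MEF and macrophage founders, and there Pou5f1 stood at 5.24±0.21 in ES against -5.21 in NSC and dim in the others, and Nanog at 6.98±0.01 in ES against -6.26 to -3.6. The gap between ES and those founders is thus not a difference between slides. The slides of the iPS arrays held no founder array, so a slide effect on the rise in the iPS cells themselves was not tested. The pre-B arrays, on other slides, and genes that differ between ES and iPS arrays have no such comparison. Whether the founder arrays came from the animals that gave the iPS cells is not stated. Pre-B and NSC founder arrays had Xist at 0.95 to 2.17 and a Y-linked mean of -4.56 to -3.9, their iPS arrays Xist at -5.35 to -2.87 and a Y-linked mean of -1.05 to 1.03. MEF founder arrays had Xist at 0.66 and 0.49 and a Y-linked mean of -1.57 and -2.1. MEF-derived p3 arrays had Xist at -1.84 and -2.22 and a Y-linked mean of -4.75 and -4.66. The pre-B, NSC and MEF comparisons thus also hold a difference in sex-linked signal between founder and iPS arrays. Macrophage founder and p3 iPS arrays had Y-linked means of 0.84 to 1.01 and 0.51 to 0.54, with Xist at -6.93 to -6.43 and -2.91 to -2.78. From pre-B cells, the small heat shock gene Hspb1 rose by 12.8±0.26 (adjusted p = 5.6e-14, 7150-fold, -4.16±0.71 to 8.65±0.09), the membrane anchor gene Pigp by 6270-fold, the epithelial secreted gene Wfdc2 by 4900-fold and the germ and pluripotent cell gene Dppa5a by at least 15200-fold. Nanog (511-fold), Pou5f1 (8.32±0.56, 319-fold), Sox2 (at least 355-fold) and Esrrb (81-fold), all of the pluripotency network, rose too, and Klf4 rose 3.72-fold, while Myc fell 34.2-fold. On preB replicates 1 and 2 Pou5f1 stood at -1.459 and -4.157 and Nanog at -1.981 and -3.883. The sizes of these 2 folds are thus uncertain beyond the pooled error. The GTPase gene Tgtp2 fell by 1850-fold, the V(D)J recombination gene Dntt by 1140-fold (-10.16±0.26, adjusted p = 5.4e-13), Vpreb1 by 930-fold, Igll1 by at least 1740-fold and Cd19 by at least 663-fold. Of 22 pre-B markers 0 rose, 21 fell and 1 was not called (median -6.83, adjusted p = 1.65e-11, 0.00792 with an estimated correlation). Marrow genes split 1, 12 and 4 (adjusted p = 0.000326, adjusted p = 0.0551 with an estimated correlation). All 19 interferon genes fell (adjusted p = 3.03e-10, adjusted p = 0.128 with an estimated correlation). In glycolysis 14 of 16 genes rose, 0 fell (adjusted p = 9.65e-07, adjusted p = 0.207 with an estimated correlation), such as the glucose transporter Slc2a3 (75.9-fold). Called genes numbered 6562 up and 7744 down, against 6007 and 4108 with normexp background correction, and 7070 in total from the 4 arrays of the comparison alone.

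From neural stem cells, the TGF-beta family gene Gdf3 rose by 11.81±0.3 (adjusted p = 2.2e-13, 3600-fold), Wfdc2 by 2190-fold and Dppa5a by 2110-fold. Sall4, a pluripotency regulator, rose by 1750-fold, Nanog by 10.43±0.44 (1380-fold) and Fgf4, a growth factor of early embryos, by at least 3620-fold. Pou5f1 rose 1240-fold and Zfp42 1080-fold, whereas Sox2 differed by 0.33±0.31 (adjusted p = 0.39), its level being 3.46±0.13 in the founder. Fabp7 fell by 11.38±0.88 (2660-fold), the receptor phosphatase Ptprz1 by 809-fold, the matrix gene Sparcl1 by 525-fold and Scrg1 by at least 922-fold. NSC markers split 0, 20 and 5 (median -4.67, adjusted p = 1.82e-12, adjusted p = 0.0976 with an estimated correlation). Interferon genes, all lower in this founder than in the others, rose here for 14 of 19, with 0 down (adjusted p = 0.000212, adjusted p = 0.272 with an estimated correlation), such as Oasl2 (27.9-fold). Markers of other cells rose alongside. Fibroblast genes were 21 up and 2 down of 29 (adjusted p = 4.85e-07, adjusted p = 0.234 with an estimated correlation) such as Col1a2 (593-fold). Macrophage genes were 17 up and 1 down of 25 (18 up adjusted over the list alone, adjusted p = 5.61e-05, adjusted p = 0.207 with an estimated correlation) such as Ctss (at least 148-fold), and Hox genes 26 up and 0 down of 37 (adjusted p = 3.5e-06, adjusted p = 0.309 with an estimated correlation). In all, 6186 genes rose and 4223 fell.

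MEF-derived cells gained Pigp (10.69±0.57, 1660-fold), the homeobox gene Rhox5 (10.69±0.43, 1650-fold), Esrrb (10.62±0.4, adjusted p = 4.3e-11, 1570-fold), Sall4 (1150-fold), Fgf4 (at least 2930-fold) and Pou5f1 (at least 990-fold), with Nanog up 829-fold and Sox2 324-fold. The largest falls were in interferon genes, Ifit3b (-9.32±0.79, adjusted p = 1.3e-07, 640-fold) and Ifit3 (325-fold), and in Mgp (-7.49±0.38, 180-fold). All 19 interferon genes fell (adjusted p = 1.64e-11, adjusted p = 0.124 with an estimated correlation). Fibroblast markers split 0, 28 and 1 (median -2.79, adjusted p = 9.07e-12, adjusted p = 0.164 with an estimated correlation): Twist2 fell 49.9-fold, Snai2 48.7-fold and Col1a1 by 2.08. Hox genes split 1, 31 and 5 (adjusted p = 1.22e-09, adjusted p = 0.207 with an estimated correlation), with Hoxd13 down 42.4-fold. Proliferation genes rose for 17 of 23 with 0 down (adjusted p = 1.8e-07, adjusted p = 0.207 with an estimated correlation), the cyclin Ccnb1 by 8.96-fold. Of the called genes, 5810 rose and 4903 fell.

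In macrophage-derived cells Nanog rose by 12.4±0.44 (adjusted p = 3.5e-12, 5410-fold), as did Pigp (3300-fold), the DNA demethylation gene Tet1 (11.66±0.28, 3250-fold), the matrix gene Sparc (11.65±0.28, 3200-fold) and, by at least 6670-fold, Dppa5a. The size of the Nanog fold is uncertain. Its founder level of -6.26±0.36 lay below the -4.86±0.51 of Pou5f1, which was dim there. Pou5f1 rose by at least 579-fold and Sox2 by at least 229-fold. Atp6v0d2 fell by 10.24±0.45 (1210-fold), Clec7a by 1110-fold, the secreted chitinase-like gene Chil3 by 688-fold, Itgax by at least 2350-fold and Csf1r by 62-fold. Macrophage markers split 1, 24 and 0 (median -5.64, adjusted p = 1.82e-12, adjusted p = 0.0976 with an estimated correlation). Marrow genes split 1, 11 and 5 (12 down adjusted over the list alone, adjusted p = 0.000597, adjusted p = 0.0551 with an estimated correlation). Fibroblast genes rose for 26 of 29 with 1 down (adjusted p = 3.7e-10, adjusted p = 0.207 with an estimated correlation), Col1a2 by 622-fold. Proliferation genes rose for 18 of 23 with 1 down (adjusted p = 2.46e-06, adjusted p = 0.221 with an estimated correlation), the mitotic gene Cdc20 by 11-fold. Called were 6676 genes up and 5790 down.

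Across the 4 reprogramming comparisons, the 31 genes of the pluripotency network moved together. From pre-B, NSC and MEF 30 rose and 0 fell (adjusted p = 3.32e-15, 4.16e-17 and 6.94e-19, adjusted p = 0.124, 0.124 and 0.112 with an estimated correlation), and from macrophages 29 and 0 (adjusted p = 3.32e-15, adjusted p = 0.124 with an estimated correlation). Epithelial adhesion genes rose for 17, 16, 15 and 16 of 17 from pre-B, NSC, MEF and macrophages, with 0 down in each (adjusted p = 2.78e-09, 1.64e-11, 2.78e-09 and 1.68e-07, adjusted p = 0.133, 0.124, 0.133 and 0.19 with an estimated correlation). Examples were the keratin Krt18 from pre-B (247-fold), the adhesion gene Cdh1 from NSC (at least 500-fold) and the adhesion gene Epcam from MEF (at least 253-fold). Germline genes rose for 18, 19, 20 and 18 of 21, again with 0 down (19 from macrophages adjusted over the list alone, adjusted p = 1.79e-08, 1.09e-10, 1.64e-11 and 1.14e-07, adjusted p = 0.207, 0.162, 0.139 and 0.207 with an estimated correlation). The meiotic gene Sycp3 rose 394-fold from pre-B and the piRNA gene Mael at least 190-fold from MEF. The DNA methylation cofactor Dnmt3l rose 1050-fold from pre-B, 1350-fold from NSC and 296-fold from MEF. Strict filtering on dim probes left 7069, 5023, 5533 and 6866 called genes, in the same order.

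Between p3 and p20, in cells of pre-B origin the SOCS box gene Spsb4 rose by 4.85±0.77 (adjusted p = 0.001, 28.8-fold), the chromatin gene Dido1 by 4.38±0.44 (adjusted p = 0.00012, 20.8-fold), Tox3 by 4.37±1.11 (20.7-fold) and the hyaluronan synthase Has2 by at least 8.98-fold (2 arrays against 2 in each passage comparison). The scavenger receptor Marco fell by 6.82±1.25 (adjusted p = 0.0024, 113-fold), the transporter Slc13a3 by 5.21±0.84 (36.9-fold), the acute phase gene Saa3 by 17.5-fold and the macrophage elastase Mmp12 by at least 5.58-fold. Fibroblast markers split 1, 10 and 18 (1 and 11 adjusted over the list alone, medians -1.08 and -1.19 within slides 4 and 5, adjusted p = 0.00155, and 0.00198 with slide as a block, adjusted p = 0.768 with an estimated correlation). The crosslinking enzyme Lox fell 7.59-fold and Col1a1 3.3-fold. Macrophage markers split 0, 5 and 20 (9 down adjusted over the list alone, within-slide medians -0.88 and -0.62, adjusted p = 0.0171, 0.0184 with slide as a block, adjusted p = 0.768 with an estimated correlation), with Adgre1 down 9.36-fold. Genes of primed and formative pluripotency rose for 5 of 16 with 0 down (7 up adjusted over the list alone, within-slide medians 0.86 and 1.5, adjusted p = 4.52e-06, 3.73e-06 with slide as a block, adjusted p = 0.576 with an estimated correlation). They included the Nodal inhibitor Lefty1 (6.13-fold) and the regulator Pou3f1 (1.97). Also called were the pluripotent cell gene L1td1 (up 6.82-fold), the imprinted RNAs Kcnq1ot1 (up 7.24-fold) and Meg3 (down 6.72-fold). In total 1511 genes rose and 861 fell, and 2288 were called with slide as a fixed block. Of the called genes 1388 passed 1 log2 unit on both slides, and over all genes the changes on the slides correlated at 0.42. The total moved to 1012 without preB iPS p3 replicate 2, 1081 without preB iPS p20 replicate 1, 1276 with normexp and 1462 with the strict filter. The split was 1966 and 596 after cyclic loess, and the 4 arrays alone called 0 (limma, unadjusted p < 0.05 for 7066).

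From MEF, the repeat protein gene Ankrd34a rose by 3.66±0.69 (adjusted p = 0.01, 12.6-fold), the homeobox gene Gbx2 by 3.41±0.86 (10.6-fold), the kidney and gonad regulator Wt1 by 6.9-fold and the signalling gene Wnt8a by at least 15.1-fold, and Myc rose 3.76-fold. The reproductive homeobox gene Rhox4a fell by 4.09±0.85 (adjusted p = 0.014, 17.1-fold), the protease inhibitor Serpinb2 by 16.6-fold, Lox by 3.67±0.54 (adjusted p = 0.0048, 12.7-fold) and Mmp12 by at least 9.94-fold. Fibroblast markers split 0, 10 and 19 (11 down adjusted over the list alone, within-slide medians -1.37 and -0.96, adjusted p = 3.98e-09, 6.67e-09 with slide as a block, adjusted p = 0.576 with an estimated correlation). Macrophage markers split 0, 2 and 23 (7 down adjusted over the list alone, -0.82 and -0.59, adjusted p = 0.000358, 0.00041 with slide as a block, adjusted p = 0.576 with an estimated correlation). Epithelial genes split 0, 4 and 13 (6 down adjusted over the list alone, -0.9 and -0.7, adjusted p = 0.000202, 0.000253 with slide as a block, adjusted p = 0.576 with an estimated correlation). Primed and formative genes were 4 up, 0 down and 12 not called (5 and 2 adjusted over the list alone, 1.09 and 1.12, adjusted p = 0.0193, 0.0217 with slide as a block, adjusted p = 0.768 with an estimated correlation), such as the methyltransferase Dnmt3b (1.84). Xist fell 6.54-fold. Pre-B and MEF origins shared 176 genes called higher (31.2 expected if independent) and 208 called lower (20.5). In all 573 genes rose and 660 fell, and 1174 were called with slide as a fixed block. Of them 874 passed 1 log2 unit on both slides, and over all genes the changes on the slides correlated at 0.37. That total was 95 without MEF iPS p3 replicate 2, 432 without MEF iPS p20 replicate 1, 47 without MEF iPS p20 replicate 2, 1966 with array weights and 0 from the 4 arrays alone (limma, unadjusted p < 0.05 for 7089).

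Few genes were called in cells of NSC or macrophage origin. From NSC, the zinc finger genes Zfp229 (1.36±0.19, adjusted p = 0.017, 2.58-fold) and Zfp296 (2.37-fold) and the microRNA host Mir17hg (2.2-fold) rose. The nuclear receptor Rora fell by 2.85±0.43 (adjusted p = 0.024, 7.2-fold), the exchanger Slc9a5 by 6.3-fold, the peptide hormone Adm by 6.09-fold and the forebrain gene Fezf1 by at least 3.29-fold. Hox genes had a median of -1.21 with 0 of 37 called (6 down adjusted over the list alone, within-slide medians -1.61 and -0.75, adjusted p = 6.03e-08, 7.95e-08 with slide as a block, adjusted p = 0.576 with an estimated correlation). From macrophages, Zfp874a, a zinc finger gene, rose by 4.55±0.33 (adjusted p = 1.5e-05, 23.5-fold), the transport gene Rab6b by 1.81±0.25 (3.5-fold) and Crisp3 by at least 2.87-fold, and the oxygen sensor Egln3 fell by 1.79±0.28 (3.47-fold). Macrophage markers had a median of -0.9 with 0 of 25 called (within-slide medians -0.06 and -1.64, adjusted p = 8.36e-05, 8.71e-05 with slide as a block, adjusted p = 0.576 with an estimated correlation). Fibroblast markers had a median of -0.48 with 0 of 29 called (1 down adjusted over the list alone, within-slide medians 0.1 and -1.14, adjusted p = 0.00155, 0.00198 with slide as a block, adjusted p = 0.768 with an estimated correlation). Genes of primed and formative pluripotency, up from pre-B and MEF, had a median of -0.36 here with 0 of 16 called (within-slide medians -0.43 and -0.31, adjusted p = 0.0277, 0.0296 with slide as a block, adjusted p = 0.768 with an estimated correlation). Whether the change of this list differs between origins was not tested. From NSC, the macrophage (0.06, adjusted p = 0.814) and fibroblast markers (-0.22, adjusted p = 0.197) did not pass. Called were 4 up and 10 down from NSC (limma, unadjusted p < 0.05 for 3829) and 7 up and 1 down from macrophages (2864), or 10 and 9 genes with slide as a fixed block. Over all genes the changes on the slides correlated at 0.18 and 0.15. These small totals moved with most settings. From NSC it was 1 with normexp, 40 after quantile normalization, 34 with the authors' values, 109 after cyclic loess, 224 with array weights, 122 without preB replicate 1 and 0 without NSC iPS p20 replicate 2. From macrophages it was 3, 64, 70 and 35 with the first 4 of these, 78 without preB replicate 1 and 24 to 110 without an array of the comparison. Splits up and down from NSC were 1 and 0 with normexp, 18 and 22 after quantile normalization and 15 and 19 with the authors' values. From macrophages they were 2 and 1, 36 and 28, and 38 and 32, and 18 and 17 after cyclic loess.

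**Figure D2:**
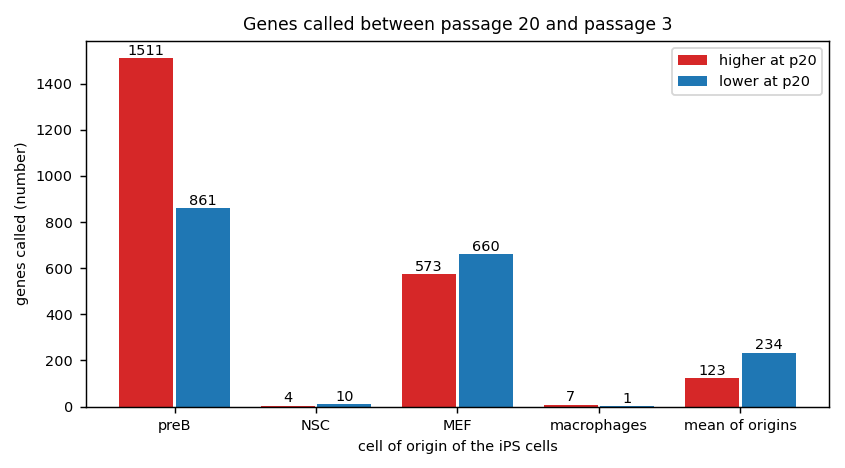
Genes called higher and lower at p20 than at p3 (number of genes, y axis) for each origin (x axis): 1511 and 861 for pre-B, 4 and 10 for NSC, 573 and 660 for MEF, 7 and 1 for macrophages.

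Averaged over the origins (8 arrays against 8), Marco fell by 3.42±0.62 (adjusted p = 0.0043), Lox by 2.01±0.27 (adjusted p = 0.001, 4.01-fold), the fetal liver gene Afp by 3.15-fold, Adgre1 by 2.89-fold, Col1a1 by 1.19±0.19 (2.29-fold) and the early response gene Ier3 by 1.14±0.12 (adjusted p = 0.00038, 2.21-fold). L1td1 rose by 1.21±0.22 (adjusted p = 0.0043, 2.32-fold), and the two-cell genes Zscan4a and Zscan4f by 1.16 and 1.12. Pou5f1 (-0.23), Nanog (0.21) and Sox2 (0.23) were not called. Fibroblast markers split 0, 4 and 25 (5 down adjusted over the list alone, median -0.81, -0.86 and -0.7 within slides 4 and 5, adjusted p = 5.01e-09, 7.85e-09 with slide as a block, adjusted p = 0.576 with an estimated correlation). Macrophage markers split 0, 4 and 21 (-0.53 and -0.52, adjusted p = 2.78e-05, 2.87e-05 with slide as a block, adjusted p = 0.576 with an estimated correlation). Epithelial genes split 0, 1 and 16 (-0.56 and -0.55, adjusted p = 0.000358, 0.00041 with slide as a block, adjusted p = 0.594 with an estimated correlation). Two-cell-like genes were 2 up, 0 down and 11 not called (5 up adjusted over the list alone, 0.79 and 0.61, adjusted p = 0.0124, 0.0127 with slide as a block, adjusted p = 0.75 with an estimated correlation). In all 123 genes rose and 234 fell, 345 with slide as a fixed block (173 past 1 log2 unit on both slides, correlation over all genes 0.25), and 0 within slide 4 or slide 5 alone (limma, unadjusted p < 0.05 for 1717 and 3594, 8 arrays each). Normexp called 95, the strict filter 74, the authors' values 136, and leaving out preB iPS p20 replicate 1 or 2 gave 229 or 546. The split was 211 and 193 after quantile normalization and 224 and 194 after cyclic loess.

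Were the iPS cells like ES cells? At p3 (8 arrays against 2, with no slide shared), genes of fibroblasts and of the immediate early response stood far above ES. Col1a2 was higher by 9.87±0.34 (adjusted p = 2e-11, 935-fold, 5.78±0.67 against -4.09±0.22), the calcium binding gene S100a4 by 9.73±0.24 (852-fold), Dcn by 9.27±0.73 (617-fold), Egr1 by 9.05±0.18 (adjusted p = 1.3e-13, 532-fold). The imprinted RNA H19 was higher by 8.94±0.29 (493-fold) and the lysozyme Lyz1 by at least 346-fold. Lower were the phosphatase inhibitor Ppp1r14d (-6.07±0.42, 67.2-fold), the defensin Defa3 (-6.02±0.68, 64.9-fold), the olfactory receptor Olfr224 (57.7-fold), the Wnt target Sp5 (-5.65±1.01, 50.1-fold) and Dcstamp (at least 24.8-fold). Within the pluripotency network 1 gene was higher, 9 were lower and 21 not called (adjusted p = 0.00982, adjusted p = 0.632 with an estimated correlation). Zfp42 was lower by 3.94±0.39 (15.3-fold), Tfcp2l1 by 7.2-fold and the threonine enzyme Tdh by 7.59-fold, and the Nodal coreceptor Tdgf1 was higher by 14.4-fold. Pou5f1 (-0.16), Sox2 (-0.32) and Nanog (-0.85) were not called. Immediate early genes were 12 higher, 0 lower and 2 not called (adjusted p = 4.68e-14, 0.0209 with an estimated correlation), with Fos at 214-fold and Fosb at 84.1-fold. Fibroblast markers split 25, 1 and 3 (adjusted p = 6.09e-17, adjusted p = 0.0893 with an estimated correlation). Macrophage markers split 19, 0 and 6 (20 higher adjusted over the list alone, adjusted p = 6.53e-13, adjusted p = 0.0709 with an estimated correlation), and interferon genes 17, 1 and 1 (adjusted p = 6.39e-12, adjusted p = 0.0893 with an estimated correlation). Hox genes split 20, 3 and 14 (21 and 3 adjusted over the list alone, adjusted p = 0.000155, adjusted p = 0.581 with an estimated correlation). Oxidative phosphorylation genes were 0 higher, 0 lower and 22 not called (down, adjusted p = 0.0068, adjusted p = 0.632 with an estimated correlation). Called were 3731 genes higher and 2738 lower, against 1732 and 1934 with normexp, 4224 in total with the authors' values and 2879 with the strict filter.

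At p20, against the same ES arrays, immediate early and matrix genes led. Egr1 was higher by 9.22±0.18 (595-fold), S100a4 by 491-fold, Col1a2 by 423-fold, Dcn by 304-fold, H19 by 231-fold and Lyz1 by at least 225-fold. Hprt, a purine salvage gene, was higher by 7.91±0.23 (adjusted p = 4.8e-12, 240-fold, 5.76±0.24 against -2.14±0.43). It is deleted in a widely used subline of E14, and the labels do not name the subline. Olfr224 (-6.60±0.45, 96.8-fold), Defa3 (64.4-fold), Sp5 (48.3-fold), Zfp42 (15-fold) and Dcstamp (at least 33.6-fold) were lower. The pluripotency network split 1, 5 and 25 (adjusted p = 0.0929). Immediate early genes were 11 higher, 0 lower and 3 not called (adjusted p = 1.44e-14, 0.0209 with an estimated correlation), with Fos at 164-fold. Fibroblast markers split 23, 1 and 5 (24 higher adjusted over the list alone, adjusted p = 6.09e-17, adjusted p = 0.0893 with an estimated correlation). Macrophage markers split 18, 0 and 7 (adjusted p = 4.19e-12, adjusted p = 0.0709 with an estimated correlation). Interferon genes split 16, 1 and 2 (17 higher adjusted over the list alone, adjusted p = 1.44e-14, adjusted p = 0.0709 with an estimated correlation). Primitive endoderm genes were 8 higher, 0 lower and 6 not called (adjusted p = 1.88e-06, adjusted p = 0.17 with an estimated correlation), such as Dab2 (at least 13.6-fold). Called were 3164 genes higher and 2006 lower, against 1442 and 1411 with normexp, 3353 in total with the authors' values and 2068 with the strict filter. As root mean square log2 distance over all genes, the founders lay 2.22 to 2.63 from ES, the p3 groups 1.46 (pre-B), 1.27 (NSC), 1.34 (MEF) and 1.31 (macrophages), and the p20 groups 1.22, 1.14, 1.18 and 1.29.

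**Figure D3:**
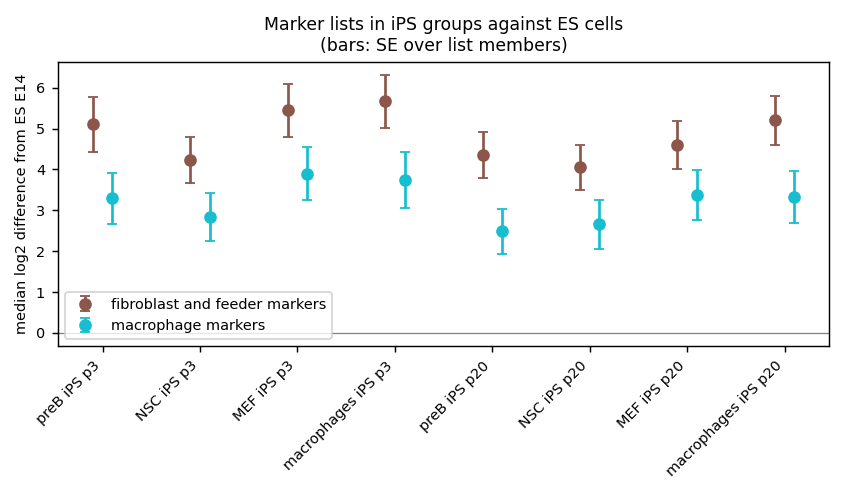
Median over list members of the log2 difference from ES (y axis) for fibroblast and macrophage markers in each iPS group (x axis): for fibroblast markers the p3 groups lay 5.11 (pre-B), 4.23 (NSC), 5.45 (MEF) and 5.67 (macrophages) above ES, and in the p20 groups 4.35, 4.05, 4.60 and 5.20.

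Did origin still show? At p3, an F test over the 4 origins put a Y-linked gene first: Eif2s3y spanned 7.96 log2 units (adjusted p = 8.3e-07), from -4.15±0.28 in MEF-derived to 3.81±0.14 in pre-B-derived cells, with 2.51±1.16 from NSC and 3.31±0.02 from macrophages. Zfp874a spanned 6.84 (adjusted p = 6.2e-08) and Crisp3 at least 4.32 (adjusted p = 3.6e-06), both lowest in macrophage-derived cells, where Crisp3 was dim. The growth factor Fgf5 spanned at least 4.38 (adjusted p = 0.0026), from dim in pre-B-derived to -0.32 in macrophage-derived cells. At p20 the leading genes were the Y-linked Eif2s3y (at least 7.73, adjusted p = 1.5e-07) and Ddx3y (at least 5.85, adjusted p = 5e-06), both dim in MEF-derived cells. Marco followed (5.97, adjusted p = 0.04, from -3.78±0.26 in pre-B-derived to 2.18±1.73 in macrophage-derived cells), as did the fibrinogen gene Fgg (at least 3.84, adjusted p = 0.0013, dim in MEF-derived cells). At each passage 7 of the 10 genes with the largest range were dim in at least 1 origin. Origins differed in 4295 genes at p3 and 736 at p20, or 4136 and 679 with slide as a fixed block. At p3 the count was 1825 without preB iPS p3 replicate 2, 2684 with normexp and 631 from the p3 arrays alone. At p20 it was 144 without NSC iPS p20 replicate 2, 1734 without preB iPS p20 replicate 1, 451 with normexp and 0 from the p20 arrays alone (limma, unadjusted p < 0.05 for 4519). As a direct measure, the root mean square spread between origins was 0.561 at p3 and 0.369 at p20. The difference was 0.191, with an exact p of 0.75 over 8 swaps of passage labels (the smallest possible being 0.125). All 8 differences were positive (0.086 to 0.368) with the preB labels held fixed, so the wider set always held the preB iPS p3 arrays. That group lay 0.82 from the other p3 origins, against 0.68 to 0.74 for the rest.

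Whether the passage change itself depended on origin was tested by the interaction of both. Of the 10 genes with the largest range 8 had a group dim on every array, and ranges are given here with such groups set no lower than the detection floor. Dach1, a developmental cofactor, spanned 2.26 between origins (adjusted p = 0.012), with changes of 1.22 from pre-B and -1.04 from NSC. Fgf5 spanned 4.39 (adjusted p = 0.032), changing by 2.48 from MEF and -1.91 from macrophages, Zfp874a 5.56 (adjusted p = 0.00036, 4.55 from macrophages and -1.01 from pre-B) and the cytokine Il17f 6.29 (adjusted p = 0.02, -3.56 from MEF and 2.73 from macrophages). The oocyte homeobox gene Obox6 spanned 6.18 (adjusted p = 0.046, -2.5 from pre-B and 3.69 from macrophages). In all, 2503 genes differed in their passage change, 2264 with slide as a fixed block. The count was 528 without preB iPS p3 replicate 2, 762 without macrophages iPS p3 replicate 2, 4664 without preB replicate 1, 1360 with normexp and 13 from the iPS arrays alone.

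**Figure D4:**
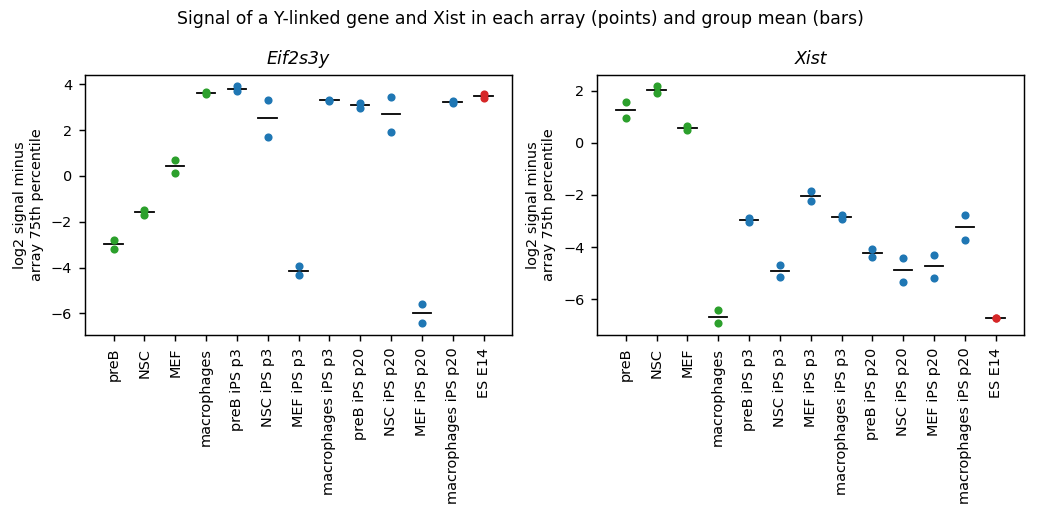
Levels of Eif2s3y and Xist on each array (log2 signal relative to the 75th percentile, y axis) by group (x axis): Eif2s3y spanned 7.96 log2 units between origins at p3 and at least 7.73 at p20, with MEF-derived cells lowest.

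Finally, genes that marked a founder were followed into the iPS cells of that origin against the other origins. These signatures (3352 genes for pre-B, 861 for NSC, 637 for MEF and 907 for macrophages, at least 2 log2 units above the other founders) were chosen on founder arrays that enter none of these iPS contrasts. The pre-B set rests on the 2 arrays with the largest shares of probes well above background (81.6 and 66.6%). It may hold dim genes, so a median near that of all genes says little on kept pre-B expression. At p3, MEF signature genes lay 0.12 higher in MEF-derived cells, where the median of all genes was -0.15 (58.2% above 0 against 35.2% of other genes, medians of 0.11 within both slides, adjusted p = 1.38e-05, adjusted p = 0.574 with an estimated correlation). Among single genes, the pattern recognition gene Ptx3 was higher by 1.47, but 2 were called higher and 1 lower. Without MEF iPS p3 replicate 1 the median was 0.04, and with normexp 0.01. Fibroblast markers too were higher in these cells than in the mean of the other origins, by 0.43 (standard error over list members 0.07). Over ES, however, macrophage-derived p3 cells lay higher (5.67) than MEF-derived ones (5.45). Feeder RNA, which stays open below, was not separated from kept expression here. The other p3 medians were 0.20 for pre-B (0.19 over all genes, direction down, adjusted p = 0.674), 0.12 for NSC (0.02 over all genes, 0.0683) and 0.07 for macrophages (-0.07 over all genes, 0.115). The pre-B median was -0.08 after quantile normalization, -0.03 with the authors' values and -0.17 after cyclic loess, and the macrophage median -0.07 with normexp and -0.1 with the strict filter. The NSC value passed at 0.11 with normexp (0.000235), and the macrophage value at 0.17 for signatures of at least 3 log2 units (0.00383). At p20, macrophage signature genes lay 0.20 higher in macrophage-derived cells (65.3% above 0 against 48.5%, slide medians 0.24 and 0.05, adjusted p = 6.85e-05, adjusted p = 0.202 with an estimated correlation). Of them 33 were called higher and 5 lower, the former including Saa3 (3.28) and the Y-linked Eif2s3y and Ddx3y, which were dim in MEF-derived cells. Without macrophages iPS p20 replicate 2 that median was 0.06 (adjusted p = 0.325). These cells also had the highest fibroblast markers over ES at p20 (5.20 against 4.05 to 4.60 in the other origins), and on that array 100 bright MEF genes lay at a median of 6.12% of their MEF level, the highest at p20. NSC signature genes lay lower in NSC-derived cells at p20, with a median of -0.16 (slide medians -0.11 and -0.2, adjusted p = 0.0357, adjusted p = 0.931 with an estimated correlation). That call was lost after quantile normalization (-0.09, adjusted p = 0.131) and without NSC iPS p20 replicate 1 (-0.11, adjusted p = 0.15). Between the passages the NSC signature changed by -0.28 (adjusted p = 0.0026, adjusted p = 0.627 with an estimated correlation) and the MEF signature by -0.07 (adjusted p = 0.00466, adjusted p = 0.627 with an estimated correlation). For pre-B (-0.10, adjusted p = 0.326) and macrophages (0.10, adjusted p = 0.198) no change was called.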

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

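The tests of feeder RNA, of slides, of kept fibroblast expression, of X-linked genes, of passage labels, of the signal distribution (with cyclic loess) and of leaving out an origin were chosen after the result was seen.

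A difference between groups was the reason for each result here: the passage change differed between origins for 2503 genes. The widest ranges of that change were in Obox6 (6.52), Il17f (6.29), Ssxb1 (6.25), Krtdap (5.97), Ssx9 (5.85), Dach1 (5.61), Ssxb7 (5.6), Zfp874a (5.56), Magea8 (5.5) and Fgf5 (5.44), all in log2 units. Of these 10 genes 8 had a group dim on every array, and with such groups set no lower than the detection floor the ranges were 2.02 to 6.29. Ssxb1, Ssx9 and Ssxb7 belong to a family of X-linked germline genes, as does Magea8 to another. The signal distribution of the arrays could account for such a pattern, but at least 71.2% of the genes were called again after quantile normalization or cyclic loess, which speaks against it. A shift between slides common to their arrays is not the reason, as 8 of 8 iPS groups have as many arrays on slide 4 as on slide 5 and it cancels in each passage change. A slide effect that differs between groups was not tested. The iPS arrays alone called 13 genes. The passage changes are the same in that fit, so the count of 2503 leans on residual spread taken also from founder and ES arrays. The preB-derived arrays do not carry the whole pattern, as over the 3 other origins 987 genes were still called in the fit to all 26 arrays. Leaving out NSC, MEF or macrophages gave 3107, 1913 and 714. How much of the 2503 rests on the preB-derived arrays cannot be told.

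Fibroblast and macrophage markers stood above ES in iPS arrays of every origin, and averaged over the origins both lists fell with passage (adjusted p = 0.576 for each with an estimated correlation), though neither passed from NSC. RNA from feeder fibroblasts in the iPS arrays stays open: of the 100 brightest MEF genes that were not well above background in ES, 83 were well above background on all p3 iPS arrays, but their levels do not imply 1 share of MEF RNA per array (array medians 1.66 to 8.46%, the 90th percentile over genes 13.7 to 44.7 times the 10th). The macrophage markers lay at a median of 20.4 to 53% of their MEF level on the p3 iPS arrays, above the 90th percentile of the bright genes on 8 of 8. But the bright genes had to be dim in ES and the markers did not. Signal of the iPS cells themselves can thus raise the markers' percent (Csf1r, for example, stood at 0.54±0.13 in ES against 3.48±0.41 in MEF). The comparison therefore cannot decide whether feeders alike to the MEF arrays account for them. Feeders of another makeup were not tested. Fibroblast expression kept by MEF-derived cells does not explain the fibroblast part. MEF-derived p3 cells exceeded the mean of the other origins by only 0.43±0.07, while those exceeded ES by 4.94±0.62. Here and in the next sentence, ± is the standard error over the 29 list members, which are correlated, and not between arrays. A difference between slides is not the source of the averaged fall of the fibroblast markers (medians -0.86±0.09 and -0.70±0.10 within slides 4 and 5, so -0.7 at the smallest). By origin those medians were -1.02 and 0.33 from NSC and 0.1 and -1.14 from macrophages. Within a slide the p3 and p20 arrays of an origin bear different replicate numbers, so these medians may also hold differences between replicates. For the part against ES it cannot be told, as ES and iPS arrays share 0 slides.

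MEF-derived iPS arrays had no Y-linked signal at p20 (0 of 3 Y genes well above background on both arrays) and little at p3, while the MEF founders lay between the others (Y mean -1.57 and -2.1, Xist 0.66 and 0.49). Female founder cells with 2 active X chromosomes in the iPS cells could give a shift of X-linked genes (683 against 16903 autosomal genes). X-linked genes were higher at p3 (camera adjusted p = 2.88e-11, 0.00284 with an estimated correlation), did not pass at p20 (adjusted p = 0.866), and the change between passages passed (adjusted p = 1.98e-06, 0.0149 with an estimated correlation). The size of the p3 shift, 0.26, lies between the bounds set for a yes (0.3) and a no (0.1), so this explanation stays open. A swap of MEF-derived arrays with another origin at a single passage is not the reason, since 0 origins changed their Y-linked state between the passages. That state was the group mean above or below the middle of the iPS range. Swaps between the passages of an origin, or among the other origins, would not show in this count.

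For the averaged passage change, 100 splits of the arrays within origin were compared, the real one among them: 3 of the 100, counting the real one (372 genes on the 16 iPS arrays alone), called at least as many, the highest 585, and 81 called 0. A split within origin can swap the passages of some origins only, and which arrays the split with 585 genes exchanged was not examined.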

How the results depend on the processing

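All alternatives but cyclic loess, array weights, leaving out preB replicate 1 and tests within a slide were chosen before the result was seen. Somatic, reprogramming and ES counts kept their size under nearly every setting (20 of 24 alternatives for each ES comparison), and passage counts from NSC and macrophages did not (4 of 18 and 6 of 18). Signal over background limits dim genes: the strict filter tests 14984 genes, no filter 34270. The cause of the moves below was not tested, except that the strict filter has fewer genes and fits of the compared groups fewer arrays.

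In the labels, samples share only a number between groups. The replicate block (correlation of same-numbered arrays at a median of 0.05 over 78 pairs of groups, -0.27 to 0.24, 21 over 0.1) moved no count past 1.5 times, for example 2378 genes for passage preB.

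Reversed: Cbx8 in somatic preB without preB replicate 1 (0.37), and Il7r (-0.07) and Hba-a1 (-0.01) in p20 against ES with normexp.

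Strict filter: somatic 5058 (preB), 3951 (NSC), 2973 (MEF), 4835 (macrophages); reprogramming 7069, 5023, 5533, 6866; passage 1462 (preB), 95 (NSC), 48 (macrophages), 74 (mean); against ES 2879 (p3), 2068 (p20). Normexp: somatic MEF 5216, passage 1276 (preB), 1 (NSC), 3 (macrophages), 95 (mean), against ES 3666 and 2853, origin 2684 (p3), 451 (p20), by passage 1360. Authors' values: passage 34 (NSC), 70 (macrophages), 136 (mean), ES 4224 and 3353. Quantile: passage 40 (NSC), 64 (macrophages). Cyclic loess: passage 109 (NSC), 35 (macrophages). Trend and robust: passage 60 (NSC), 32 (macrophages), origin p20 1211. Mean of probes: passage NSC 8. Array weights: somatic preB 8204, passage 224 (NSC), 1966 (MEF), origin p20 1525. No filter: origin p20 391, by passage 1487. Adjusted p only: somatic MEF 12565, passage 4776 (preB), 2339 (MEF), 3166 (mean), ES 11667 and 9881, origin p3 7026. Compared groups only: reprogramming preB 7070, origin p3 631, by passage 13, and 0 for origin p20 (limma, 4519 with unadjusted p < 0.05) and passage preB (7066), NSC (3844), MEF (7089) and macrophages (2224). Within slide 4 and within slide 5: averaged passage 0 and 0 (1717 and 3594).

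Founder signatures (median, adjusted p): NSC p3 passed with normexp 0.11 (0.000235), no filter 0.13 (0.0135), strict filter 0.17 (0.000302), authors' values 0.13 (0.00032), array weights 0.15 (0.0241) and at log2 3 0.16 (0.0421), macrophages p3 at log2 3 0.17 (0.00383). NSC p20 was lost with quantile -0.09 (0.131), cyclic loess -0.08 (0.25) and an estimated correlation -0.16 (0.931), as with the last were MEF p3 0.12 (0.574) and macrophages p20 0.2 (0.202). Medians of the other sign: preB p3 -0.08 (quantile), -0.03 (authors), -0.17 (loess), preB p20 -0.02, -0.01 and -0.07, MEF p20 0.01 (quantile), 0.03 (loess), macrophages p3 -0.07 (normexp), -0.1 (strict filter). Camera with estimated correlation passed 15 list tests.

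Leaving out 1 array at a time, with its lone partner assumed to vary like other groups: passage preB 1012 to 3289, NSC 0 to 202 (limma, unadjusted count for 3829 genes with all arrays), MEF 47 to 1833, macrophages 24 to 110, mean 229 to 546, origin p3 1825 to 5804, p20 144 to 1734, by passage 528 to 4664, founder preB p3 0 to 0.35, NSC p3 0.02 to 0.15, MEF p3 0.04 to 0.17, macrophages p3 0.02 to 0.09, preB p20 -0.09 to 0.25, MEF p20 -0.08 to 0.04, NSC p20 -0.24 to -0.11, macrophages p20 0.06 to 0.27.

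Median shifts of all genes over 0.1 under a scaling: somatic preB -0.46 (quantile), -0.33 (authors), -0.11 (loess), NSC 0.17 (quantile), 0.12 (authors), MEF 0.24, 0.14, 0.15; reprogramming preB -0.18 (loess), NSC -0.27, -0.11, -0.2, MEF -0.23 (quantile), -0.24 (loess), macrophages -0.15 for both; passage preB 0.15 (loess); ES p3 -0.17 and p20 -0.14 (quantile).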

Other observations

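The test of cell lines in the last paragraph was chosen after the result was seen.

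Beyond the pluripotency network, some lists of other early states rose in reprogramming, in some origins. The two-cell embryo gene Zscan4f rose by at least 105-fold from pre-B, at least 287-fold from NSC, 102-fold from MEF and at least 61.1-fold from macrophages. Two-cell-like genes were 9 up, 0 down and 4 not called from pre-B (camera adjusted p = 0.00613, adjusted p = 0.301 with an estimated correlation), 10, 0 and 3 from NSC (0.00132, adjusted p = 0.234 with an estimated correlation) and from MEF (0.00167, adjusted p = 0.241 with an estimated correlation), and 7, 1 and 5 from macrophages (0.101). Trophoblast genes rose for all 9 from NSC (adjusted p = 7.78e-05, adjusted p = 0.207 with an estimated correlation) and for 8 of 9 with 0 down from macrophages (adjusted p = 0.00269, adjusted p = 0.301 with an estimated correlation), with the regulator Tfap2c up 323-fold and at least 249-fold, but did not pass from pre-B (0.124) or MEF (0.257). Genes of primed and formative pluripotency were 8 up, 2 down and 6 not called from pre-B (adjusted p = 0.0452, adjusted p = 0.579 with an estimated correlation), 10, 2 and 4 from MEF (adjusted p = 0.000832, adjusted p = 0.318 with an estimated correlation) and 13, 1 and 2 from macrophages (adjusted p = 6.63e-06, adjusted p = 0.207 with an estimated correlation). From NSC they did not pass (0.107). Among them the homeobox gene Otx2 rose 446-fold, 999-fold and 1770-fold from pre-B, MEF and macrophages, and the TGF-beta family gene Nodal 95.1-fold from pre-B and 79.7-fold from MEF. Polycomb genes from macrophages were 10 up, 3 down and 3 not called (adjusted p = 0.0295, adjusted p = 0.324 with an estimated correlation), led by Pcgf6 (9.38-fold). Primitive endoderm genes were 9, 2 and 3 from pre-B (adjusted p = 0.04, adjusted p = 0.469 with an estimated correlation), 11, 0 and 3 from NSC (12 up adjusted over the list alone, adjusted p = 0.000722, adjusted p = 0.234 with an estimated correlation), 11, 1 and 2 from macrophages (adjusted p = 6.72e-05, adjusted p = 0.207 with an estimated correlation), and 3, 5 and 6 from MEF (0.195). Early lineage regulators passed from no origin (0.176 to 0.888).

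Some neural regulators stood above ES in the iPS arrays. The oligodendrocyte regulators Olig1 and Olig2 were higher by at least 57.8-fold and at least 16.9-fold at p3, and by at least 85.2-fold and at least 28.1-fold at p20. NSC markers split 9 higher, 2 lower and 14 not called at p3 (10 and 2 adjusted over the list alone, adjusted p = 0.0146, adjusted p = 0.581 with an estimated correlation) and 10, 3 and 12 at p20 (11 and 3 adjusted over the list alone, adjusted p = 0.00456, adjusted p = 0.581 with an estimated correlation), where the median of 0.65 was -0.03 with normexp. Genes of differentiated neural cells were 1 higher, 2 lower and 8 not called at both passages (adjusted p = 0.613 and 0.554).

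Founder arrays of pre-B cells and NSC had Xist at 0.95 to 2.17 and a Y mean of -3.9 to -4.56, while their iPS arrays had Xist at -2.87 to -5.35 and a Y mean of -1.05 to 1.03. NSC iPS replicate 1 was lower in Y signal than replicate 2 at both passages (-1.05 and -0.91 against 0.96 and 0.72). The imprinted gene Mest, chosen after its values were seen, differed between the NSC iPS replicates by 8.25 at p3 and 6.24 at p20.

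If same-numbered arrays of an origin came from 1 line at both passages, replicate differences at p3 should recur at p20. Of genes that differed by at least 2 log2 units at both, 89 kept their sign and 35 did not within an origin, against 275 and 109 between different origins. The exact one-sided p over the 24 matchings of origins was 0.5, so pooled over the origins the test does not show that same-numbered arrays come from 1 line at both passages. It does not exclude it either, least of all for NSC, where differences such as Mest and the Y signal recurred by number, since a count pooled over origins says little on 1 of them.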
